A study of Mus musculus with 10 samples.

How the data were processed

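RNA was measured by sequencing in 10 liver libraries of 20-week-old C57BL/6 mice, 5 in a group titled NAFL and 5 in a group titled NASH. Per the labels' protocols, total RNA was extracted with Trizol from frozen liver and libraries were made with the Illumina TruSeq RNA kit, which does not mark the strand of a transcript. Reads from exons that overlap on opposite strands therefore cannot be told apart. Among the genes named below, some overlap the span of another gene model with a mean count of at least 10. They are Acadvl with Dvl2, Alas2 with Apex2, Cdc20 with Elovl1, Cela2a with Casp9 and Cyp2a4 with Gm42375. The others are Il18bp with Numa1, Klf12 with 4930517O19Rik, Plin4 with Hdgfl2, Tm7sf2 with Vps51 and Zdhhc2 with Cnot7. Strands and exons of these pairs were not compared, so how far they share reads is not known. Samples were assigned to groups from their titles, and each sample's diet was read from its treatment label.

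Each sample has 1 file with a count and an FPKM value for each of 55968 gene models, some of which carry no Ensembl identifier. The deposited counts are whole numbers per gene, without normalization, per the file headers and the values. The deposited FPKM values were made by the authors from the counts, the gene length in the same file and 1 depth constant per library, as the values themselves show. HISAT2 2.0.5 and the builds mm10 and mm8 are named in the submitters' processing notes, with no role given for either build. The gene counter, its settings and the annotation release are not given in the sources used here. Of the 55471 Ensembl genes in the files, 55230 were found in GENCODE mouse release 21, and 99.5% of these had the same chromosome, start and end there, so coordinates are given as mm10. How the authors' counting treated reads that match several genes is not given in the sources used here, so genes with near-identical copies (the Mup, Cyp2a, Cyp2c, Cyp3a and Serpina1 clusters, and ribosomal protein genes with their pseudogenes) are uncertain as single genes.

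The authors also deposited 1 table of the NAFL and NASH comparison with 9993 genes. Its p-values, per the file header, are the authors' own, and it holds only genes with an unadjusted p of at most 0.05. Its log2 fold changes, per the file header and the values in the authors' deposited table, are NAFL over NASH, so that a negative value means higher in NASH. Its normalized signal per sample, deposited by the authors, equals the deposited count times 1 constant per library within 1% for all of its genes except 2, Klf10 and Atp6v0d2. The table was used only for this check and for the values quoted from it.

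Integrity of the sample files was checked in the same way. From count and FPKM, the gene length used in the FPKM was computed for 14188 genes with at least 20 counts in any library. It lay within 2% of the length in the file for all but 2 of them, Zdhhc7 and Isg15. The counts of these rows were analysed as labelled, and an alternative with their counts exchanged was added after seeing the data.

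Genes were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, as fixed before the data were examined. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 13791 genes with 99.8% of all counts. Libraries were scaled by TMM, and the quasi-likelihood F-test compared NASH with NAFL over all 10 libraries with no covariate. Calls were made at a Benjamini-Hochberg adjusted p of 0.05. All fold changes below are NASH over NAFL. The standard error of a log2 fold change was computed as its size divided by the square root of F. Expression is given as CPM (edgeR) of the TMM-scaled library, as mean ± SD over 5 libraries. Against a group with 0 counts a fold is a lower bound, computed with 3 counts over the group in place of 0. With 1 to 3 counts in a group the ratio is given with a 95% exact (Clopper-Pearson) interval. These intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules. The p-values of single genes measure the spread between these samples, and the labels do not say in words that each sample is a separate mouse. Camera sets the genes of a list against all other genes, and the tests of symbol stems count genes as units. Those p-values do not measure the spread between samples alone.

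Before the data were examined, 34 gene lists with 663 symbols were fixed, of which 662 were found. They cover liver cell types, matrix, inflammation, lipid, bile acid and drug metabolism, hepatocyte zonation, stress, sex-biased liver genes, the KLF and ZDHHC families, and signs of sampling or RNA quality. For each list the members that rose or fell were counted, over all genes tested and adjusted over the list alone. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 34 lists. Camera with an estimated correlation and fry were alternatives. Camera compares a list with all other genes, while fry tests whether the members move on balance in 1 direction.

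The genes named in the text were chosen by a rule fixed in advance. It took Klf10 and Zdhhc7, and the 6 genes that rose most and the 6 that fell most among called genes whose groups do not overlap, with a mean CPM of at least 5, leaving out predicted genes, pseudogenes and immunoglobulin or T cell receptor segments. From each list it took the 1 to 3 members with the largest called changes and a mean CPM of at least 1, or, where none of these was called, the member with the smallest p. This gave 77 genes, of which 2 are not reported here as single genes, and any other gene named was chosen after its values were seen.

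Each library was counted as a replicate by its title. Pairs within a group had a chi-square per degree of freedom of 10.6 to 62.1 over genes with at least 20 counts, which does not show whether they are separate mice. Alternatives were DESeq2 1.42.0, other scalings and filters, limma-voom, limma on log2(FPKM + 1), leaving out each library in turn, the replicate number as a block, a 2-fold minimum and removal of the 50 genes with most counts. The removed genes were not tested and were left out of the lists, which left 13744 genes tested. Added after seeing the data were the exchange of the Zdhhc7 and Isg15 counts, the exchange of the Klf10 and Atp6v0d2 counts, removal of the genes of chromosome MT, removal of NASH libraries 1, 2 and 4, and removal of each library's trend with gene length (loess on log2 length). The same tests were run on simulated counts for 13945 genes, drawn from the means and library sizes of the NASH and NAFL comparison with 200 genes changed. They recovered 36% of 50 genes changed 1.5-fold, 96% of 50 changed 2-fold and 100% of 50 changed 4-fold and of 50 changed 8-fold. Of 179 calls, 13 (7.26%) were genes left unchanged. All simulated genes had the same dispersion, and far fewer genes changed than the 8019 called in the data. These rates therefore do not carry over to the real comparison. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 was used to read the files.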

Results

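Liver RNA of 20-week-old C57BL/6 mice, an inbred laboratory strain, was sequenced in 10 libraries from 2 models of fatty liver disease. The 5 NAFL libraries came from mice fed a high fat diet for 12 weeks. The 5 NASH libraries came from mice given a regimen labelled WD with CCl4 (carbon tetrachloride, a solvent toxic to hepatocytes), whose duration is not given in the sources used here. Diet and toxin differ together between the groups, and no libraries of untreated mice were analysed here. The files hold 15926578 to 18187526 counts per library, 16293792 ± 481915 (SD, n = 5) in NAFL and 16826942 ± 846905 (SD, n = 5) in NASH. NASH libraries had a count in 20963 ± 291 (SD, n = 5) gene models and NAFL libraries in 19361 ± 190 (SD, n = 5). Mitochondrial transcripts took 6.59% ± 0.61 (SD, n = 5) of the counts in NAFL and 9.39% ± 2.88 (SD, n = 5) in NASH, where libraries 1, 2 and 4 held 11.8%, 9.50% and 12.6% and libraries 3 and 5 held 6.12% and 6.90%.

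The comparison of the groups asks how the liver transcriptome of the NASH model differs from that of the NAFL model, with attention to Klf10 and Zdhhc7, which the series title names. Genes of extracellular matrix, recruited macrophages, the cell cycle and the female-biased liver programme rose in NASH livers, as counted by calls per gene. By the same counts, genes of lipogenesis, bile acid handling, resident Kupffer cells and the male-biased liver programme fell. Such counts do not test a list as a whole, since of all 13791 genes tested 4110 rose and 3909 fell. As whole lists, 15 of the 34 passed camera with the preset correlation and 0 with an estimated correlation (2 at unadjusted p under 0.05). Of 13791 genes tested, 8019 changed (edgeR quasi-likelihood test, adjusted p of at most 0.05), 4110 rising and 3909 falling, and 2764 of them changed at least 2-fold. The values of the groups did not overlap for 5820 genes (42.2%), where chance gives 0.794%. The first principal component of log2 CPM held 67.3% of the variance and separated the groups. The share of calls that rose was 51.3%, with a median log2 fold change over all tested genes of 0.05. With upper quartile factors that median was 0.17, and with library sizes alone it was 0.25 and 67.0% of the calls rose. The majority turned with the gene length trend removed, where 45.5% of the calls rose, and with limma on log2(FPKM + 1), where 47.0% rose. It also turned without NASH libraries 1, 2 and 4, where 48.7% rose. The plot of list members by call shows the 34 gene lists side by side.

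**Figure D1:**
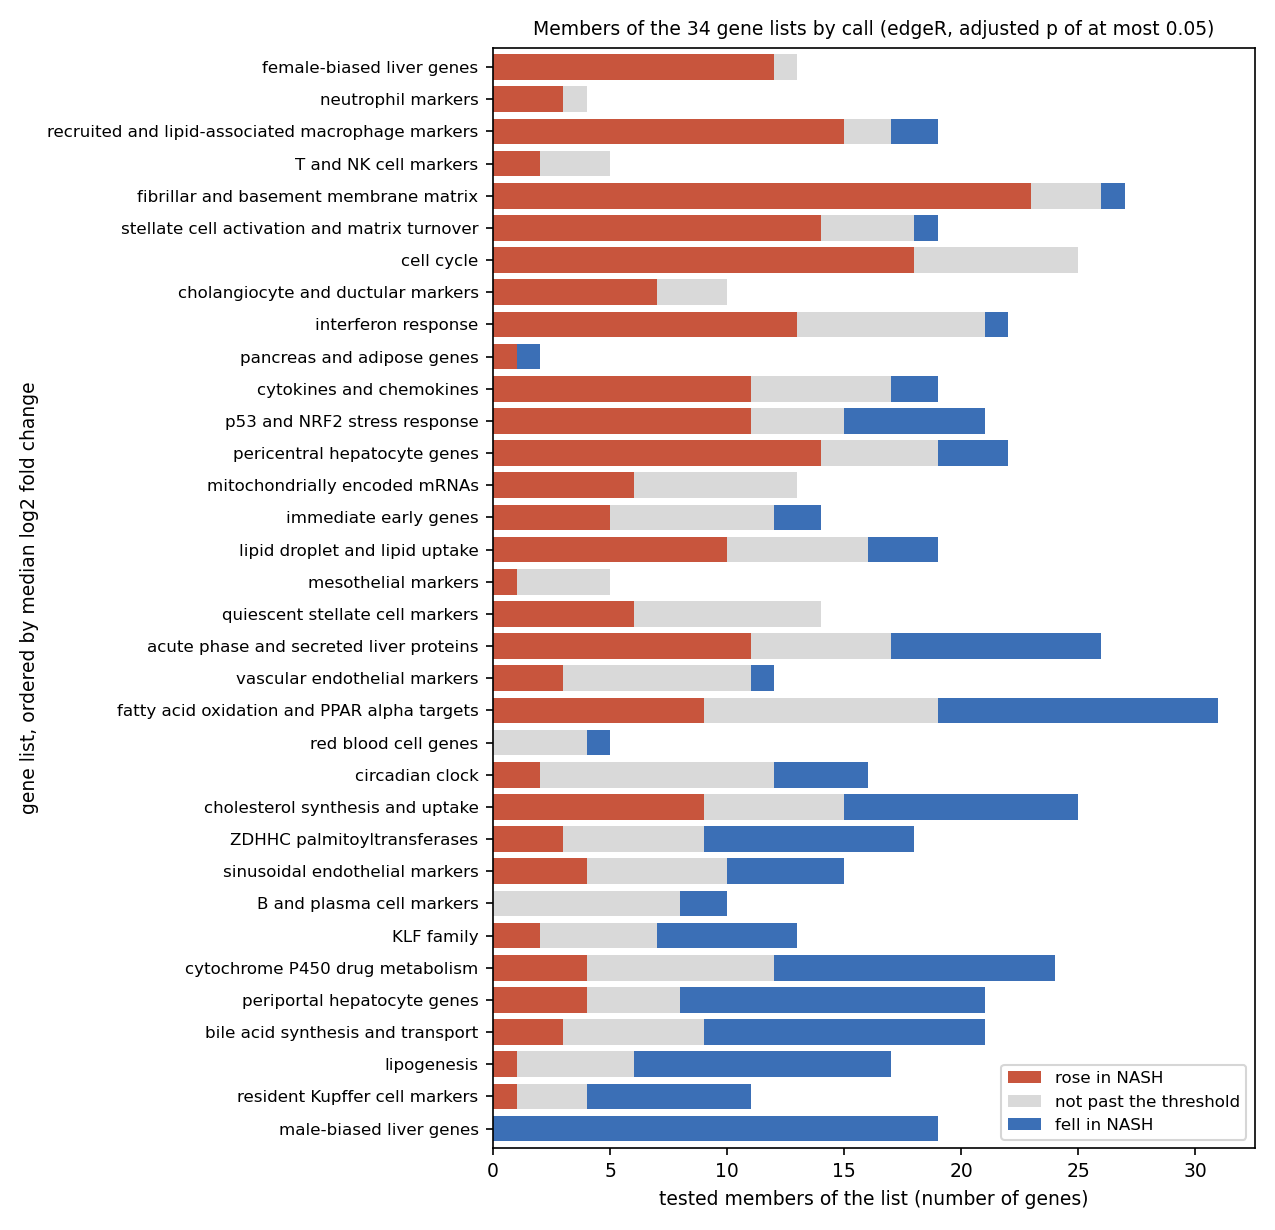
Number of tested members of each of the 34 gene lists (x axis, genes) that rose in NASH, fell in NASH or did not pass the threshold (edgeR, adjusted p of at most 0.05), with lists ordered by median log2 fold change. All 19 tested male-biased liver genes fell, 12 of 13 female-biased genes rose (11 with the counts of Klf10 and Atp6v0d2 exchanged), and 23 of 27 matrix genes rose.

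Klf10 (ENSMUSG00000037465, mm10 chromosome 15, 38291463 to 38300706, minus strand), a Krüppel-like transcription factor, was lower in NASH by its deposited counts, with a large spread between NAFL libraries. Its counts were 979 ± 656 (SD, n = 5) in NAFL, ranging from 362 to 1963, and 599 ± 215 (SD, n = 5) in NASH, ranging from 349 to 911. The log2 fold change was −0.95 (SE 0.39, edgeR adjusted p = 0.0476), and the call ended in 7 of the 10 fits that leave out 1 library, those without NAFL 1, 4 or 5 or NASH 1, 3, 4 or 5. Without NAFL library 4 the log2 fold change was −0.54 (edgeR adjusted p = 0.197). The authors' deposited table lists Klf10 in the opposite direction, at 24.9 in NAFL and 828 in NASH, with a log2 NAFL over NASH of −5.07 and an adjusted p of 4.35e-117. Those values equal the scaled counts of the row labelled Atp6v0d2, a subunit of the vacuolar proton pump, in the sample files. Which of the deposits carries the wrong label was not fully settled here, and to that extent the direction of Klf10 stays open. The rows of Klf10 and Atp6v0d2 in the authors' deposited table departed by at least 11.5% from count times the library's constant in all 20 values, and after exchange of the rows the largest departure was 0%. By its counts Atp6v0d2 (ENSMUSG00000028238, chromosome 4, 19876841 to 19922605, minus strand) rose from 22.6 ± 10.2 (SD, n = 5) to 918 ± 107 (SD, n = 5), a log2 fold change of 5.09 (SE 0.22, edgeR adjusted p = 1.03e-09). The FPKM values in the sample files imply gene lengths of 4179 bp for Klf10 and 2716 bp for Atp6v0d2, which are the lengths listed for them. These lengths argue against an exchange of finished rows, count and FPKM together, in the sample files. An exchange of counts before FPKM was computed would leave the lengths as listed, so it was not excluded.

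The row labelled Zdhhc7 (ENSMUSG00000031823, chromosome 8, 120080890 to 120101482, minus strand), a gene for a protein palmitoyltransferase, was higher in NASH, but its values may not be those of Zdhhc7. Its counts were 82.8 ± 15.8 (SD, n = 5) in NAFL and 554 ± 112 (SD, n = 5) in NASH, a log2 fold change of 2.50 (SE 0.16, edgeR adjusted p = 3.17e-08), with all 5 NASH libraries above all 5 NAFL libraries. Its FPKM implies a gene length of 703 bp in all 10 libraries, whereas its listed length is 3677 bp. The row labelled Isg15 (ENSMUSG00000035692, chromosome 4, 156199455 to 156200796, minus strand), an interferon-induced ubiquitin-like protein, implies 3677 bp and is listed at 703 bp. Its counts were 291 ± 51.6 (SD, n = 5) in NAFL and 286 ± 64.5 (SD, n = 5) in NASH, with a log2 fold change of −0.26 (SE 0.15, edgeR adjusted p = 0.138). With the gene length trend removed the row labelled Isg15 was at −0.57 and passed (edgeR adjusted p = 0.00469). If the counts of these rows are exchanged, Zdhhc7 has the log2 fold change of −0.26 (edgeR adjusted p = 0.138) and Isg15 that of 2.50. The authors' deposited table lists Zdhhc7 with the values of the row so labelled, 89.4 in NAFL and 498 in NASH.

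**Figure D2:**
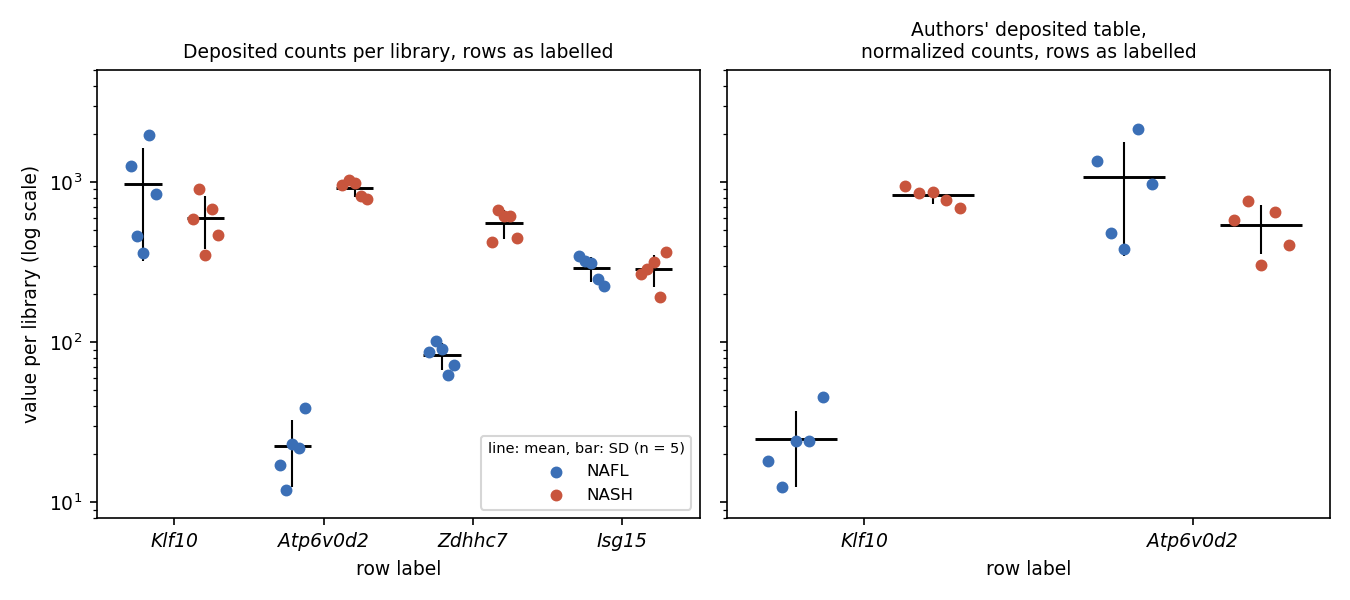
Values per library on a log axis for the NAFL (blue) and NASH (red) groups, with the mean (line) and SD (bar, n = 5), for 4 rows of the deposited counts on the left and 2 rows of the authors' deposited table (normalized counts) on the right, all as labelled. On the left Klf10 has means of 979 and 599 and Atp6v0d2 of 22.6 and 918, and on the right the values of these rows are exchanged.

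Among the families of these genes, more members fell than rose. Of 13 tested KLF factors, 6 fell, Klf10 as labelled among them, and 2 rose, the same counts adjusted over the list alone. With the counts of Klf10 and Atp6v0d2 exchanged, 5 fell and 3 rose. Klf12 fell by 1.35 on the log2 scale (SE 0.18) and Klf6, an injury-induced factor, rose by 1.73 (SE 0.21). Of 18 tested ZDHHC palmitoyltransferases, 9 fell and 3 rose, the latter including the row labelled Zdhhc7, and the counts were the same adjusted over the list alone. With the counts of Zdhhc7 and Isg15 exchanged, 9 fell and 2 rose. Zdhhc14 fell by 1.65 (SE 0.24) and Zdhhc2 by 1.62 (SE 0.27), and reads of Zdhhc2 may include those of the overlapping Cnot7. Neither family passed camera (adjusted p = 0.285 for KLF and 0.263 for ZDHHC).

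Matrix genes rose in NASH livers. Of 27 tested fibrillar and basement membrane genes 23 rose and 1 fell, with a median log2 fold change of 1.24. Col1a1, the main chain of fibrillar collagen, went from 3.91 ± 1.79 CPM (SD, n = 5) to 16.6 ± 6.13 CPM (SD, n = 5), 4.26-fold (log2 2.09, SE 0.30, edgeR adjusted p = 4.14e-05). Thbs1, the matrix glycoprotein thrombospondin, rose 4.92-fold (log2 2.30, SE 0.42), and Col15a1, a collagen of basement membrane zones, fell by 0.91 (SE 0.25). Of 19 tested genes of stellate cell activation and matrix turnover 14 rose and 1 fell. Mmp12, macrophage elastase, rose 82.2-fold (log2 6.36, SE 0.97), from 26 counts over the NAFL libraries to 2684 over the NASH libraries. Its call ended with limma-voom (log2 5.47, limma-voom adjusted p = 0.0520). S100a6 rose 4.24-fold (log2 2.08, SE 0.30). Itgav, an integrin subunit, fell by 0.49 (SE 0.11), a call that ended without NASH libraries 1, 2 and 4 (edgeR adjusted p = 0.0512) and with library sizes alone (edgeR adjusted p = 0.0551). Of 14 markers of quiescent stellate cells 6 rose and none fell. Counts in all 3 lists were the same adjusted over the list alone. Camera gave adjusted p = 9.82e-06 for matrix and 0.00179 for stellate activation, and with an estimated correlation adjusted p = 0.627 and adjusted p = 0.529. The quiescent list did not pass camera (adjusted p = 0.0598), but did without NAFL library 1 or 5 or NASH library 1 (camera adjusted p of 0.0156 to 0.0440).

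Macrophage markers moved apart. Of 11 tested markers of resident Kupffer cells 7 fell and 1 rose, while of 19 markers of recruited and lipid-associated macrophages 15 rose and 2 fell, the same counts adjusted over the list alone. Timd4, a phosphatidylserine receptor of embryo-derived Kupffer cells, fell from 4.17 ± 1.06 to 1.03 ± 0.65 CPM (SD, n = 5 each), a log2 change of −2.01 (SE 0.38). C6, a complement component on the Kupffer list that hepatocytes also express and that the male-biased list holds as well, fell by 2.80 (SE 0.22), and Il18bp rose by 0.61 (SE 0.14), with reads that may be shared with the overlapping Numa1. Gpnmb, a glycoprotein of lipid-laden macrophages, had 2 counts over the NAFL libraries and 2621 over the NASH libraries, a ratio of 1110 (95% exact interval 307 to 9174). NASH library 2 held 1366 of the latter, and without it the fitted log2 fold change of Gpnmb, which depends on the prior count, went from 9.69 to 8.97. Lgals3, galectin-3, rose 12.8-fold (log2 3.68, SE 0.57). These genes varied widely within NASH: Gpnmb had 18 and 31 counts in libraries 1 and 4, and 1366, 917 and 289 in libraries 2, 3 and 5, and Mmp12 had 34 and 57 against 1224, 844 and 525. Adgre1, which encodes the macrophage antigen F4/80, fell by 1.24 (SE 0.33), a call that ended without NASH libraries 1, 2 and 4 (edgeR adjusted p = 0.106). Camera gave adjusted p = 0.0433 for the Kupffer list and 0.00179 for the recruited list, and both had adjusted p = 0.627 with an estimated correlation. The Kupffer list missed the threshold with DESeq2 (camera adjusted p = 0.0748), without NAFL library 1 (camera adjusted p = 0.0521) and without members shared between lists (camera adjusted p = 0.104).

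Of 19 tested cytokines and chemokines 11 rose and 2 fell, the same adjusted over the list alone. Ccl2, which attracts monocytes, rose 18.5-fold (log2 4.21, SE 0.32) and Ccl22 33.0-fold (log2 5.04, SE 0.64), the latter from 4 counts over the NAFL libraries to 181, and at a log2 of 6.39 without NAFL library 5. Cxcl12 fell by 0.64 (SE 0.10). The list lay just inside the threshold of camera (adjusted p = 0.529 with an estimated correlation), and missed it without NASH library 2, 3 or 5 (camera adjusted p of 0.0570 to 0.0678), with upper quartile factors (0.0896) and with library sizes alone (0.106). With the gene length trend removed 10 of its members rose and 6 fell. Of 4 neutrophil markers tested, out of 13 listed, 3 rose, led by S100a8 (log2 2.15, SE 0.57), whose group values overlapped. Of 5 T and NK cell markers tested, out of 20 listed, 2 rose, Trac and Trbc2, named after their values were seen. Of 10 B and plasma cell markers 2 fell over all genes and 0 adjusted over the list alone. The neutrophil, T and NK, and B and plasma cell lists did not pass camera (adjusted p = 0.237, 0.367 and 0.607). Ighm fell by 1.25 (SE 0.43), and without NAFL library 5 its log2 fold change was −0.69 and the call ended (edgeR adjusted p = 0.104).

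Lipid synthesis genes fell. Of 17 tested lipogenesis genes 11 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.00179, and adjusted p = 0.529 with an estimated correlation). Scd1, the desaturase that makes oleate, fell from 10724 ± 2417 CPM (SD, n = 5) to 178 ± 57.4 CPM (SD, n = 5), a log2 change of −5.91 (SE 0.28, edgeR adjusted p = 1.80e-09). Acly, which makes cytosolic acetyl-CoA, fell by 1.87 (SE 0.16), and Fads2, a desaturase of polyunsaturated fatty acids, rose by 1.29 (SE 0.25). Of 19 genes of lipid droplets and lipid uptake 10 rose and 3 fell (11 and 3 adjusted over the list alone), with Cidec at 6.08-fold (log2 2.60, SE 0.30) and Plin4 at 5.51-fold (log2 2.46, SE 0.26), both droplet coat proteins, and with Pparg falling by 0.97 (SE 0.19). Genes of cholesterol synthesis and uptake went both ways, 9 rising and 10 falling of 25 (9 and 11 adjusted over the list alone). Hmgcs1, which makes HMG-CoA, rose by 1.71 (SE 0.22), while Idi1 fell by 1.80 (SE 0.19) and Tm7sf2, a sterol reductase, by 1.16 (SE 0.13). Of 31 genes of fatty acid oxidation and PPAR alpha targets 12 fell and 9 rose, the same adjusted over the list alone. Acadvl, the very-long-chain acyl-CoA dehydrogenase, fell by 1.70 (SE 0.26) and Acot1 by 1.51 (SE 0.35), while Fgf21, a hepatokine, rose 30.4-fold (log2 4.93, SE 0.49). The median of this list was 0.02, its mean 0.27 and its camera direction down (adjusted p = 0.900). Neither the droplet list (camera adjusted p = 0.109) nor the cholesterol list (camera adjusted p = 0.607) passed.

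Genes of bile acid handling and drug metabolism fell. Of 21 tested genes of bile acid synthesis and transport 12 fell and 3 rose, the same adjusted over the list alone (camera adjusted p = 0.00179, and adjusted p = 0.529 with an estimated correlation). Slco1a1, an organic anion uptake carrier, fell from 703 ± 118 to 59.9 ± 10.2 CPM (SD, n = 5 each), a log2 change of −3.55 (SE 0.16). Cyp7b1, an oxysterol hydroxylase of the alternative bile acid pathway, fell by 2.23 (SE 0.16), and Abcc4, an export pump, rose by 1.10 (SE 0.26). Slco1a1 and Cyp7b1 are also members of the male-biased list. Of 24 cytochrome P450 and drug metabolism genes 12 fell and 4 rose (12 and 5 adjusted over the list alone), with Cyp2c54 falling by 3.10 (SE 0.49), Cyp2c29 by 2.59 (SE 0.13) and Cyp2a4 rising. The median of the P450 list was −0.53 and its mean 0.003 (camera down, adjusted p = 0.0433, and adjusted p = 0.627 with an estimated correlation), and the list missed the threshold without NASH library 2 (camera adjusted p = 0.0875).

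Hepatocyte genes of the pericentral zone mostly rose and those of the periportal zone mostly fell. Of 22 pericentral genes 14 rose and 3 fell, and of 21 periportal genes 13 fell and 4 rose, the same adjusted over the list alone. Rhbg, an ammonium transporter of pericentral hepatocytes, rose 9.85-fold (log2 3.30, SE 0.36) and Lect2, a secreted hepatokine, 3.37-fold (log2 1.75, SE 0.12). Hsd17b6 fell by 2.04 (SE 0.25) and Etnppl by 1.89 (SE 0.22), both on the periportal list, on which Apoc2 rose by 2.31 (SE 0.22). Cyp2c29, which fell, is on the pericentral list. The pericentral list did not pass camera (adjusted p = 0.0940), but did without NAFL library 5 or NASH library 1 (camera adjusted p of 0.0416 and 0.0410). The periportal list did (adjusted p = 0.0345, and adjusted p = 0.627 with an estimated correlation), and its call ended without NASH library 2 (camera adjusted p = 0.0561) and without NASH libraries 1, 2 and 4 (camera adjusted p = 0.0702).

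Among the gene lists, the male-biased and female-biased ones had the median log2 fold changes of largest size. The single genes that rose or fell most were not all on these lists. They include Gpnmb of the recruited macrophage list (fitted log2 9.69) and Scd1 of the lipogenesis list (log2 −5.91). All 19 tested male-biased liver genes fell, with a median log2 fold change of −2.99, and 12 of 13 tested female-biased genes rose, with a median of 3.45, the same counts adjusted over the list alone. Atp6v0d2 as labelled is among these 12, and with the counts of Klf10 and Atp6v0d2 exchanged 11 rose and 1 fell, with a median of 3.07. That median was also 3.45 with Cyp3a44, the member with 0 NAFL counts, at its bound. Mup7, a major urinary protein, fell from 4583 ± 1631 to 148 ± 119 CPM (SD, n = 5 each), a log2 change of −4.95 (SE 0.51), and of −5.55 without NASH library 1. Cyp3a44 had 0 counts over the NAFL libraries and 1758 over the NASH libraries, and Cyp2a4, a steroid hydroxylase, rose from 1.65 ± 1.28 to 491 ± 411 CPM (SD, n = 5 each), a log2 change of 8.21, and of 8.80 without NAFL library 1. Sult1e1, the oestrogen sulfotransferase, had 3 counts over the NAFL libraries and 20666 over the NASH libraries, a ratio of 5837 (95% exact interval 1997 to 28305). All 3 of these counts lie in NAFL library 5, and without it Sult1e1 had 0 NAFL counts, so the ratio rests on that library. Vmn2r3, of the vomeronasal receptor family, had 0 counts in NAFL and was at least 1057-fold higher. Besides Scd1, the genes that fell most were Mup17, Mup18, Mup19, Mup15 and Serpina1e, with log2 fold changes of −10.39, −9.91, −8.59, −8.35 and −6.56. Leaving out 1 library moved Mup19 to −7.44 (without NAFL library 5) or −9.22 (without NASH library 1), and without NASH library 1 Mup15 was at −9.15 and Serpina1e at −7.25. Camera gave adjusted p = 9.45e-14 for the male-biased and 3.53e-07 for the female-biased list, and both had adjusted p = 0.114 with an estimated correlation. Of the male-biased members 4 are on other lists (C6, Cyp2d9, Cyp7b1 and Slco1a1), and of the female-biased members 4 (Cyp2a4, Cyp2b9, Cyp4a14 and Prom1).

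**Figure D3:**
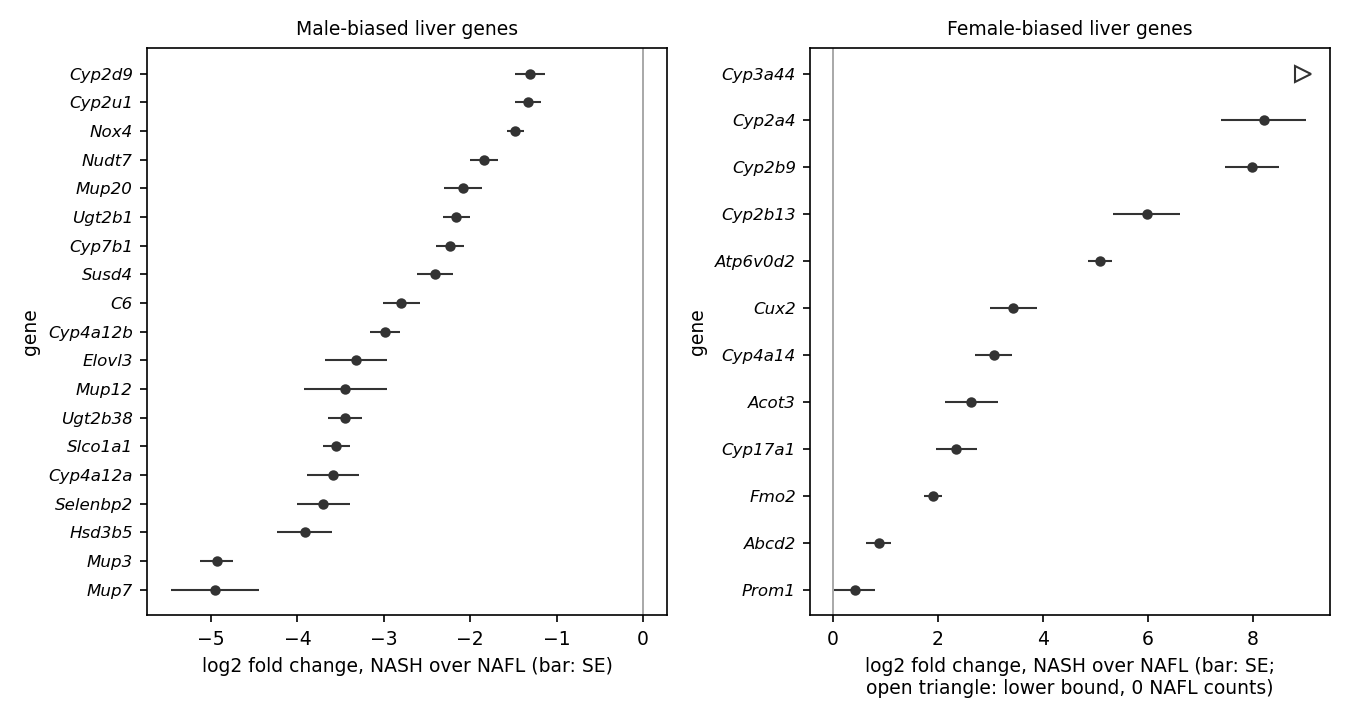
Log2 fold change, NASH over NAFL (x axis, with SE as bars, 5 libraries per group), of members of the male-biased list on the left and the female-biased list on the right. All 19 male-biased genes lie below 0 and the 12 female-biased genes shown lie above it as labelled (Atp6v0d2 at −0.95 if its counts and those of Klf10 are exchanged), Prom1 (0.42) being the member not past the threshold, and the open triangle for Cyp3a44 is a lower bound since NAFL had 0 counts.

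Cell cycle genes rose. Of 25 tested members 18 rose and none fell (19 and 0 adjusted over the list alone), with Ccnb1, cyclin B1, at 5.95-fold (log2 2.57, SE 0.41) and Cdc20, an activator of the anaphase-promoting complex, at 5.19-fold (log2 2.38, SE 0.52), whose reads may include those of the overlapping Elovl1. Camera gave adjusted p = 0.00199, and adjusted p = 0.627 with an estimated correlation. Of 21 genes of the p53 and NRF2 stress responses 11 rose and 6 fell, the same adjusted over the list alone, with Cdkn1a, the cell cycle inhibitor p21, at 11.1-fold (log2 3.48, SE 0.47), Phlda3 at 4.16-fold (log2 2.06, SE 0.33) and Txnrd1 falling by 0.64 (SE 0.08). That list did not pass camera (adjusted p = 0.227).

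Of 22 tested interferon response genes 13 rose and 1 fell, the same adjusted over the list alone. The row labelled Isg15 is among the 8 not called, and with the Zdhhc7 and Isg15 counts exchanged 14 rose. Usp18, which removes ISG15 from proteins, rose 4.89-fold (log2 2.29, SE 0.20) and Gbp3, a guanylate-binding protein, 3.24-fold (log2 1.70, SE 0.16). Bst2 fell by 0.46 (SE 0.12), a call that ended with library sizes alone (edgeR adjusted p = 0.130) and without NASH libraries 1, 2 and 4 (edgeR adjusted p = 0.0572). Camera gave adjusted p = 0.00494, and adjusted p = 0.627 with an estimated correlation. Secreted and acute phase proteins went both ways, 11 rising and 9 falling of 26 (11 and 10 adjusted over the list alone, camera adjusted p = 0.399). Lcn2, lipocalin-2, rose 166-fold (log2 7.38, SE 0.56) and Apcs, serum amyloid P, 13.2-fold (log2 3.72, SE 0.26), while Saa4 fell by 1.06 (SE 0.11). Of 14 immediate early genes 5 rose and 2 fell, the same adjusted over the list alone, led by Myc at 20.9-fold (log2 4.38, SE 0.29). Camera gave that list adjusted p = 0.0479, and adjusted p = 0.627 with an estimated correlation, and the call ended without NAFL library 2 (camera adjusted p = 0.199), NASH library 2 (0.0875) or NASH library 4 (0.0505), and with upper quartile factors (0.0859) or library sizes alone (0.106). Of 16 circadian clock genes 4 fell and 2 rose (3 and 2 adjusted over the list alone, camera adjusted p = 0.367), Nfil3 falling by 0.92 (SE 0.24).

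Some markers of other cell types and of RNA quality were also called. Over all genes 8019 of 13791 tested were called, so a few called members do not set a list apart. Of the lists in this paragraph only the ductular one passed camera in the main fit. Of 10 cholangiocyte and ductular markers 7 rose (8 adjusted over the list alone), with Epcam at 3.40-fold (log2 1.76, SE 0.32, camera adjusted p = 0.00511 for the list, and adjusted p = 0.529 with an estimated correlation). Its members with the highest CPM, Krt8 (mean 227 to 574 CPM) and Krt18 (142 to 385 CPM), were called. Krt19, Sox9 and Prom1 were not called over all genes. These members were named after their values were seen, and the cells in which the list rose were not determined. Of 15 sinusoidal endothelial markers 5 fell and 4 rose, the same adjusted over the list alone, Kdr falling by 0.89 (SE 0.19). Of 12 vascular endothelial markers 3 rose and 1 fell (2 and 1 adjusted over the list alone). Cd34 rose by 1.13 (SE 0.42), a call that ended without NAFL library 2 or 3 or NASH library 1 or 3, with edgeR adjusted p up to 0.102 and log2 fold changes of 0.85 to 1.39 over the 10 fits that leave out 1 library. Of 5 mesothelial markers 1 rose, Wt1, named after its value was seen. Of 5 red blood cell genes 1 fell, Alas2, by 1.64 (SE 0.12), and of 2 pancreas and adipose genes Cela2a rose by 2.21 (SE 0.44) and Cela1, named after its value was seen, fell. The counts of these last 3 lists were the same adjusted over the list alone, and the endothelial, mesothelial, red blood cell and pancreas lists did not pass camera (adjusted p of 0.455 to 0.900). Of 13 mitochondrially encoded mRNAs 6 rose, the same adjusted over the list alone (camera adjusted p = 0.0944), with mt-Co2 at 3.89-fold (log2 1.96, SE 0.43, and log2 1.26 without NASH library 4). The list's median went from 0.62 to −0.06 without NASH libraries 1, 2 and 4. Those libraries had the highest mitochondrial shares in NASH, so a lower median follows from the choice and tests nothing. Only NASH libraries 3 and 5 remained in that fit. Without NASH library 3 the list passed camera (adjusted p = 0.00974).

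Fold changes also followed gene length. The median log2 fold change was 0.35 among the 2759 shortest tested genes (24 to 2107 bp) and −0.20 among the 2757 longest (7302 to 123179 bp). The slope of log2 CPM, centred per gene over the 10 libraries, on log2 gene length was 0.0589 ± 0.0345 (SD, n = 5) in NAFL and −0.0589 ± 0.0111 (SD, n = 5) in NASH, with no overlap between libraries of the groups (exact permutation test, two-sided p = 0.00794, the smallest that 252 assignments can give). With the trend removed per library, 7782 genes changed, and those calls include 87.5% of the 8019.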

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

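The tests on the exchanged rows of the authors' table, on the length implied for the row labelled Zdhhc7, on female animals and on reads shared with pseudogenes were chosen after the results were seen, as was the fit with the gene length trend removed. The test planned for pseudogenes, the median of the protein-coding ribosomal genes (0.70), was replaced because these genes would share the same reads, so that it excludes nothing.

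Samples far from the rest of their group were sought with Dixon's ratio (the gap to the nearest other sample divided by the group's range, set against its 95% critical value for 5 samples) in 157 groups of values, and 10 passed, where chance passes about 5%. In NAFL, library 5 was high for Alas2 (ratio 0.766), Rhbg (0.749) and Saa4 (0.744). Library 4 of NAFL was low for Gbp3 (0.762) and Timd4 (0.738), and it was high for total counts (0.719) and for the share of counts from albumin (0.739), which was 9.71% against at most 8.74% in the others. NAFL library 2 was low for Cdkn1a (0.715). In NASH, library 2 was high for the number of genes with a count (0.831), at 21478 against at most 20893. NASH library 1 was high for Tm7sf2 (0.787), at 68.6 CPM against 42.1 to 46.7.

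The deposited values of the title genes are at odds with their labels. In the authors' table the Klf10 and Atp6v0d2 rows hold each other's values, since after exchange all 20 values equal count times the library's constant (departure 0%). In the sample files the FPKM of these rows implies their own lengths, 4179 and 2716 bp. That argues against an exchange of finished rows there, but not against an exchange of counts before FPKM was computed. Which of the deposits carries the wrong labels therefore stays open in part. For the row labelled Zdhhc7, count and FPKM imply a length of 703 bp, that of Isg15, in every library, which is consistent with counts and FPKM of these genes having been exchanged together. Within groups the row labelled Zdhhc7 followed the mean of 21 other interferon genes with r = 0.755 (exact permutation p = 0.0320, Benjamini-Hochberg 0.0640 over 2 relations, Spearman's rho 0.673 with permutation p = 0.0512, r = 0.496 without the 2 farthest libraries, n = 10 libraries), and the row labelled Isg15 with r = 0.293 (permutation p = 0.425, rho 0.176 with p = 0.666, r = 0.196 without the 2 farthest). The difference of r was 0.462 (permutation p = 0.341), so that an exchange of both values cannot be told apart from an exchange of the lengths alone with counts in place, because that difference did not pass the threshold.

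Male-biased genes fell and female-biased genes rose. Female animals among the NASH libraries are argued against by Ddx3y, a Y-linked gene, whose lowest NASH library kept 0.669 of the NAFL mean, and by Xist, which stayed at or under 0.815 CPM in all 10 libraries. The scaling of libraries is argued against by the male-biased median, which was −2.79 at most over 4 scalings, and the female-biased one, which was 3.44 at least with rows as labelled. A hypothesis of lower growth hormone and STAT5 signalling cannot be told apart from its absence, since 2 of 5 genes tested for it fell, Igf1 (log2 −0.55) and Ghr (−1.46), while Socs2 (11.2 to 45.1 CPM) and Cish (1.78) rose and Igfals was at −0.08. Diet and CCl4, which the design names together, stay open and could not be tested apart.

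Ribosomal protein genes rose: 65 of 81 tested protein-coding members rose and none fell, with a median log2 fold change of 0.70. A trend with gene length as the whole cause is argued against by the fit with the trend removed per library, in which 57 of the 81 rose and 1 fell. After removal of the trend from the fold changes, the median of 158 symbols with a ribosomal stem was 0.47, which none of 10000 sets of genes matched on length reached. Those symbols were matched by name, so pseudogenes and S6 kinase genes are not left out. The random sets hold unrelated genes and do not allow for members that share reads or move together. Reads shared with processed pseudogenes cannot be told apart from a rise of the genes themselves, since shared reads would move both sets alike. The median of the 81 members differed by −0.00107 from that of the other 77 symbols, which need not all be pseudogenes. A change in RNA quality between groups that acts on these transcripts beyond their length stays open, as does the regimen of the NASH group.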

How the results depend on the processing

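Exchange of the Zdhhc7 and Isg15 counts or of the Klf10 and Atp6v0d2 counts, removal of chromosome MT, removal of NASH libraries 1, 2 and 4, and removal of the gene length trend were chosen after seeing the data, and the other settings before. The direction of the named genes held under all settings run, except that with the counts exchanged Zdhhc7 went to −0.26 and Isg15 to 2.50, and Klf10 to 5.09 and Atp6v0d2 to −0.95, by construction. In the other settings Klf10 (−0.95) stayed negative, but it missed the threshold with DESeq2 (−0.97), upper quartile factors (−0.82), library size only (−0.73), mean CPM of at least 1 (−0.94), limma-voom (−0.75) and limma on log2(FPKM + 1) (−0.70), with adjusted p of 0.0531 to 0.155, and it ranged from −1.19 to −0.54 when each library was left out in turn. The cause was not tested. Other named genes whose calls ended somewhere were Adgre1, Bst2, Cd34, Ighm, Itgav and Mmp12 (limma-voom, 5.47, adjusted p = 0.0520).

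The 8019 changed genes were 2764 with a 2-fold minimum, 1712 rising and 1052 falling, by construction. Leaving out each library gave 7625 to 8008, DESeq2 8120, and removal of NASH libraries 1, 2 and 4 6645 with fewer samples. Of 34 gene lists 15 passed camera with the preset correlation, 0 with an estimated correlation (2 at unadjusted p under 0.05) and 23 with fry. Among the 15, the estimated correlation ran from 0.050 (cytokines) to 0.563 (recruited macrophages) and was 0.465 for matrix, against the preset 0.01. The preset p-values of these lists thus assume less correlation than was estimated. Other causes of the differences were not tested. Leaving out each library gave 11 to 17 lists. Besides the cases given with the results, calls ended with limma on log2(FPKM + 1) for the Kupffer, cytokine and periportal lists (camera adjusted p = 0.0638) and the P450 list (0.0754), without the 50 genes with most counts for the cytokine, immediate early, P450 and periportal lists (0.0521), with mean CPM of at least 1 for the P450 list (0.0527) and with the gene length trend removed for the Kupffer, cytokine and immediate early lists (0.0541 to 0.0657). The cytokine list also missed with the replicate block (0.0534) and without chromosome MT (0.0511), and the Kupffer (0.0701) and immediate early lists (0.157) without NASH libraries 1, 2 and 4. Calls were gained by the pericentral list without members shared between lists, the droplet (0.00630), pericentral (0.0233) and quiescent stellate lists (0.0162) without NASH libraries 1, 2 and 4, the quiescent list with no filter (0.0311), and the quiescent (0.0440) and mitochondrial lists (0.0385) with the block. Same-numbered libraries of the groups did not vary together (correlations of −0.11 to 0.05, and 1 of 5 matched best with its own number), so the numbers pair nothing. A fit with the replicate number as a block called 7719 genes.

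Other splits of the 10 libraries, 100 drawn with the real one, gave at most 1 changed gene against 8019. Only 1 of the 100 (the real one) gave as many. Each other split mixes NAFL and NASH libraries, so the difference between the groups widens the spread within its sets and keeps calls few. The splits therefore do not show how many calls chance alone would give. For lists passing camera with the preset correlation, 30 of the 100 gave at least the real 15 and the highest other gave 21, so chance cannot be excluded for that count. Members were also counted by the test per gene. Those counts do not replace a test of lists, since members can move together and 4110 of all 13791 genes tested rose and 3909 fell. Pseudocounts and filters planned for files with only normalized values were not run because the files hold counts. In simulated counts with 200 changed genes 36% of 1.5-fold changes were recovered, and depth was not varied.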

Other observations

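The family counts and the genes named here were looked at after the main results were seen.

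Families of genes with a shared symbol stem were counted for 225 stems with at least 8 tested genes (Fisher's exact test per stem and direction, 450 tests, Benjamini-Hochberg), and 11 stems passed 0.05. The small nucleolar RNA host genes rose in full, 13 of 13 tested Snhg genes with a median log2 fold change of 1.21 (adjusted p = 2.17e-05). Of the cytosolic ribosomal stems, 63 of 83 Rpl genes rose (median 0.75, adjusted p = 2.10e-15) and 42 of 68 Rps genes (median 0.58, adjusted p = 1.02e-05). These stems do not leave out pseudogenes, nor does Rps leave out S6 kinase genes. Of the mitochondrial ribosomal stems, 29 of 50 Mrpl (median 0.38) and 18 of 28 Mrps genes (median 0.39) rose. With the gene length trend removed, 12 of the 13 Snhg genes rose and the Mrpl and Mrps medians were 0.18 and 0.24. The stem H, which joins histone and histocompatibility genes, had 27 of 45 rising. Among stems that fell were the glucuronosyltransferases, 13 of 16 Ugt genes (median −1.66, adjusted p = 0.00127), the hydroxysteroid dehydrogenases, 10 of 12 Hsd genes (median −0.69, adjusted p = 0.00605), and the major urinary proteins, 14 of 16 Mup genes (median −3.20, adjusted p = 1.24e-04). Deubiquitinases of the stem Usp (28 of 44, median −0.46) and phosphatase genes of the stem Ppp (30 of 61, median −0.36) also fell more often than other genes. With library sizes alone 19 Usp genes fell and 5 rose, and 15 Ppp genes fell and 17 rose. Genes of a stem share reads where they are near-identical and are not independent, so these p-values are too small.

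Other genes chosen after their values were seen also moved. Nupr1, a stress-induced chromatin protein, rose by 5.83 on the log2 scale (SE 0.29, edgeR adjusted p = 2.75e-09), from 1.01 ± 0.24 to 58.1 ± 22.1 CPM (SD, n = 5 each). Mt1, a metallothionein, rose by 5.27 (SE 0.47), Gpat3, an acyltransferase of triglyceride synthesis, by 4.84 (SE 0.30), and Apoa4, an apolipoprotein, by 4.25 (SE 0.25). Bcl6, a repressor of transcription with a role in sex-biased liver expression, fell by 2.93, and Cux2, a homeobox factor of the female-biased list, rose by 3.45.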
